A study of Homo sapiens with 24 samples.

How the data were processed

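Total RNA from LNCaP and C4-2B cells was hybridised to 24 Illumina HT-12 bead arrays, 1 array per sample and 3 per group. Per the labels' protocols, cells were kept in RPMI with fetal bovine serum and given DMSO or EPZ6438 at 1 µM, or transfected with a control siRNA or an siRNA against EZH2 (1 siRNA is named), for 3 days, and RNA was isolated with a PureLink kit and labelled with biotin. The labels number the replicates but do not say whether they were separate cultures, so the p-values measure the spread between these arrays, which may be technical. DMSO and siControl cultures belong to separate experiments, and no control array served both an siRNA and an inhibitor comparison. The tests of differences between treatments or lines use the same control arrays again.

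The authors deposited a table of intensity values that were not normalised, with a detection p-value for each probe and array, and a processed table of intensity values. The submitters' processing notes name GenomeStudio and give no version. Read from the values, the deposited intensities that were not normalised are linear and without background subtraction, and the detection p-value moves in steps that imply 769 negative controls. Read from the values, the processed table is linear, background subtracted and quantile normalised (column medians of 4.2, lowest value −14.3), and each of its columns keeps the rank order of its array. The link of columns to samples comes from the labels, and no column was left unmatched.

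The intensities that were not normalised were analysed in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. They were background corrected and quantile normalised on the log2 scale with neqc, with the detection p-value standing in for negative controls and an offset of 16, which shrinks the fold changes of dim probes. Of 47311 probes, 30108 are listed with 1 gene, 8 with several and 17195 with none, and 30069 were matched by Entrez ID. A probe was kept if detected (p under 0.05) on at least 3 of the 24 arrays, which left 26278 probes, 18826 of them with 1 gene and 7449 unnamed. For each gene the kept probe with the highest mean over all arrays was used, which gave 13789 genes, of which 3852 had more than 1 kept probe. The other kept probes of called genes had the same sign as the one used in 81%, 84.7%, 86.6% and 83.1% of cases (siEZH2 in LNCaP and C4-2B, EPZ6438 in LNCaP and C4-2B). Y-linked genes and XIST were left out. Genes without a probe assigned in the annotation used were not analysed here, and 1 gene planned for every comparison is therefore not reported here.

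A linear model with 1 mean per group was fitted to all 24 arrays (lmFit and eBayes, 16 residual degrees of freedom, 7.62 prior degrees of freedom), and 9 comparisons were taken from it. They were siEZH2 against siControl and EPZ6438 against DMSO in each line, the difference between these effects within each line, the difference of each effect between lines, and C4-2B against LNCaP over DMSO and siControl arrays. Adjusted p-values follow Benjamini and Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. A fold against a group in which no array detected the gene was written as at least the fold over the detection level of that group. The genes named are the 10 highest and 10 lowest called genes of each treatment comparison and of the control cells whose arrays did not overlap between groups, 5 and 5 for each difference, up to 4 called members of each list (2 where none was called), and EZH2. Genes named outside this rule, in the comparison of all 4 treatments and in the closing part on deep decreases, were chosen after their values were seen.

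The 20 gene lists were written, with the comparisons, tests, naming rule and most alternatives, before the data were examined. They are PRC2 components, androgen-induced, androgen-repressed, reported EZH2-repressed, mitosis, DNA replication, p53 target, interferon-stimulated, cholesterol synthesis, stress response (ATF4 and unfolded protein), neuroendocrine, basal and luminal prostate epithelium, fibroblast and mesenchymal, blood and immune cell, cancer-testis antigen, cytosolic ribosomal protein, immediate early and heat shock, oxidative phosphorylation and hypoxia genes. Some genes stand on more than 1 list. Each list with at least 5 measured members was tested against all other genes with camera (2-sided, preset correlation of 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and counts were also adjusted over the list alone. List calls in the results held with an estimated correlation unless an adjusted p with it is given. Sets of genes lowered or raised in both lines were tested against the lists with Fisher's exact test.

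The fit was tested on simulated data in which 200 of 13789 genes were changed, as many up as down. Independent noise was added to normalised gene means, so background correction and normalisation were not tested. Changes of 0.5 on the log2 scale were called for 51% to 64% of genes in the treatment comparisons and for 20% in the difference between treatments in LNCaP, changes of 1 for 98% to 100% and 84%, and 7 to 13 unchanged genes were called. Alternatives were no background correction, median centring in place of quantile normalisation, the authors' processed values on a log2 scale, a stricter filter (p under 0.01 on 12 arrays) and no filter, the mean of all kept probes of a gene, eBayes with trend and robust variance, a fit of the compared arrays alone, a 1.5-fold threshold, the replicate number as a block, and each replicate number left out. Each single array left out, and centring on the 14362 probes detected on all arrays, were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.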

Results

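RNA was measured on 24 bead arrays from a pair of human prostate cancer cell lines, LNCaP, which depends on androgen, and its derivative C4-2B, which grows with little androgen. Each line was given the solvent DMSO or EPZ6438 (tazemetostat, an inhibitor of the methyltransferase activity of EZH2) at 1 µM, and, in other cultures, a control siRNA (siControl) or an siRNA against EZH2 (siEZH2), for 3 days. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3. This made 8 groups of 3 arrays. Between 19304 and 21653 of 47311 probes were detected per array (40.8% to 45.8%), and 13789 genes were compared. Changes are given as log2 differences ± standard error (SE) of the limma fit with 3 arrays in each group, and the number of arrays limits the precision. The p-values are adjusted over all genes unless a list is named. The first principal component held 44.5% of the variance and separated the cell lines, with LNCaP arrays between −38.0 and −20.6 and C4-2B arrays between 23.8 and 38.2. The second held 21% and separated the siRNA cultures from the DMSO and EPZ6438 cultures.

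The siRNA lowered EZH2 mRNA and the inhibitor did not measurably do so. EZH2 (Entrez 2146; GRCh38.p14, chromosome 7, 148807383 to 148884291) fell by 0.86 ± 0.16 on the log2 scale with siEZH2 in LNCaP (adjusted p = 0.000176) and by 1.01 ± 0.16 in C4-2B (adjusted p = 6.87e-05). With EPZ6438 it differed by −0.12 ± 0.16 in LNCaP (adjusted p = 0.737) and by 0.00 ± 0.16 in C4-2B (adjusted p = 0.997). Mean log2 intensities in LNCaP were 6.69 ± 0.01 (SD, n = 3) with siControl and 5.82 ± 0.10 with siEZH2, and in C4-2B 7.48 ± 0.26 and 6.48 ± 0.32. DMSO and EPZ6438 means were 7.13 ± 0.16 and 7.02 ± 0.07 in LNCaP, and 7.18 ± 0.10 and 7.17 ± 0.36 in C4-2B. The other EZH2 probes gave −0.96 and −0.86 with siEZH2 in LNCaP, and −1.09 and −0.92 in C4-2B. One of them gave −0.57 and −0.55 with EPZ6438 in LNCaP and C4-2B, which did not pass the test (adjusted p = 0.147 and 0.113). Among the other PRC2 components, JARID2, an accessory subunit, rose by 1.22 ± 0.12 in LNCaP and 1.13 ± 0.12 in C4-2B with siEZH2. With centring on the array median the siEZH2 change was −0.64 in LNCaP (adjusted p = 0.0536) and −0.69 in C4-2B (adjusted p = 0.0533).

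**Figure D1:**
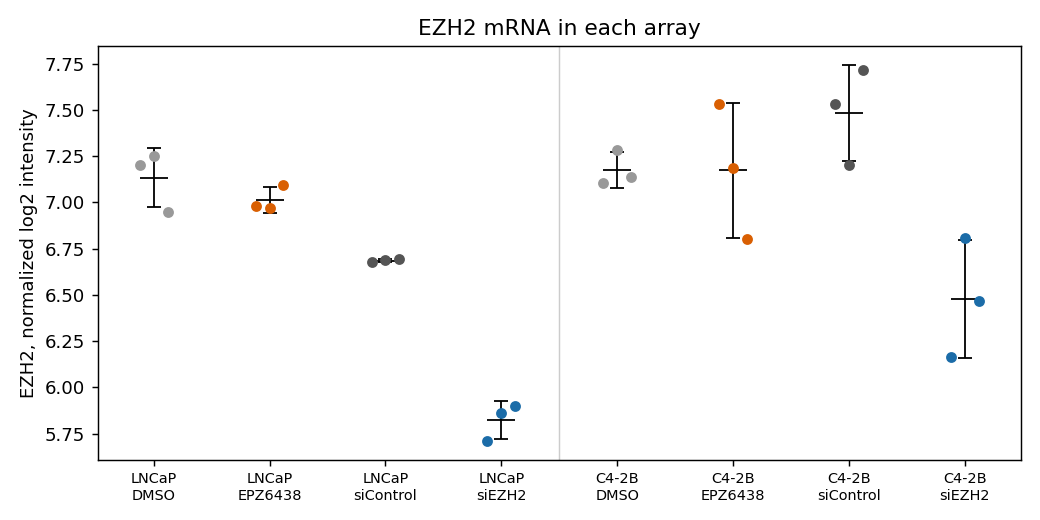
Normalised log2 intensity of EZH2 on each array (points, 3 per group; lines, group mean ± SD), by cell line and treatment. The siEZH2 means of 5.82 in LNCaP and 6.48 in C4-2B lay below the siControl means of 6.69 and 7.48.

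The siRNA against EZH2 was compared with siControl in LNCaP to find the genes that follow the lowering of its mRNA. Interferon and antiviral genes were among those that rose most. The chemokine gene CCL5 rose by 3.54 ± 0.24, the antiviral genes OASL by 3.29 ± 0.13, IFIT2 by 2.71 ± 0.14, IFIT1 by 2.55 ± 0.18 and RSAD2 by 2.18 ± 0.13. The chemokine gene CXCL10 rose by 2.45 ± 0.14. IFNB1, which encodes interferon beta, was undetected on the 3 siControl arrays (4.42 ± 0.07, SD, n = 3) and detected on the 3 siEZH2 arrays (6.71 ± 0.09), a rise of at least 4.55-fold. IGFBP3, whose product binds insulin-like growth factors, rose by 2.88 ± 0.15, and PLAAT4, a retinoid-induced gene, by 2.31 ± 0.16. The largest decreases were in PKM, a glycolytic enzyme (−2.45 ± 0.18), ARF1, a GTPase of Golgi traffic (−2.44 ± 0.09), and TARP, a T cell receptor gamma transcript of prostate cells (−2.13 ± 0.13). They were followed by FKBP5, an androgen-induced cochaperone (−2.08 ± 0.11), KRT19, a keratin of luminal cells (−1.96 ± 0.14), and YWHAE, a 14-3-3 protein (−1.95 ± 0.21). TRIM49D1 (−2.02 ± 0.20), TRIM48 (−1.90 ± 0.15), TRIM51 (−1.90 ± 0.14) and TRIM49D2 (−1.89 ± 0.23) also fell, members of a family with shared sequence that a probe may not separate. The ribosomal RNA gene RNA28SN5 rose by 3.14 ± 0.81 (adjusted p = 0.00497), with a wide spread within both groups (6.69 ± 0.69 with siControl and 9.83 ± 1.65 with siEZH2, SD, n = 3). Its call was lost without replicate 1 of each group (2.41, adjusted p = 0.0818).

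Of the 42 interferon-stimulated genes measured, 34 rose and 2 fell with siEZH2 in LNCaP (36 and 2 adjusted over the list alone, median 0.88, adjusted p of the list = 6.94e-24). Of 35 androgen-induced genes none rose and 30 fell (1 and 30 adjusted over the list alone, median −0.94, adjusted p of the list = 2.45e-24). FKBP5 fell most, followed by HERC3 (−1.74 ± 0.15), SLC45A3, a prostate solute carrier (−1.57 ± 0.14), and EAF2 (−1.54 ± 0.15). Of 23 luminal prostate epithelium genes 1 rose and 17 fell (2 and 17 adjusted over the list alone, median −0.55, adjusted p of the list = 5.88e-09). They included AZGP1 (−1.50 ± 0.12) and SPDEF, a luminal transcription factor (−1.42 ± 0.17). Of 11 androgen-repressed genes 6 rose and none fell (7 and 0 adjusted over the list alone, median 0.40, adjusted p of the list = 0.000164). The androgen-glucuronidating enzymes UGT2B17 and UGT2B15 rose by 2.09 ± 0.14 and 2.05 ± 0.27, and OPRK1 by 1.59 ± 0.10. Of 39 DNA replication genes 2 rose and 10 fell (2 and 10 adjusted over the list alone, median −0.19, adjusted p of the list = 0.00765). RRM2 changed by −1.21 ± 0.17 and the flap endonuclease FEN1 by −0.99 ± 0.17. The replication call was lost with an estimated correlation (adjusted p = 0.583), with median centring, where the median turned to 0.085 (adjusted p = 0.0707), and with centring on detected probes (adjusted p = 0.0643).

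The remaining 15 lists did not pass the list test with siEZH2 in LNCaP, though single members moved. Of 24 reported EZH2-repressed genes 7 rose and 3 fell (7 and 4 adjusted over the list alone, adjusted p of the list = 0.202). IGFBP3 and PLAAT4 were among those that rose, with NKD2 (0.97 ± 0.17) and TIMP2 (0.79 ± 0.13). Of 38 mitosis genes 9 rose and 8 fell (11 and 8 adjusted over the list alone, adjusted p = 0.76). CENPF changed by −1.31 ± 0.14, BIRC5, known as survivin, by −1.04 ± 0.10 and the cyclin CCNB1 by 0.83 ± 0.12. Of 26 p53 target genes 6 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.202), SESN1 by 1.49 ± 0.10. Of 25 hypoxia genes 3 rose and 7 fell (4 and 7 adjusted over the list alone, adjusted p = 0.53). NDRG1 changed by −1.34 ± 0.23, BNIP3 by −1.34 ± 0.13 and ADM by 1.10 ± 0.17. Of 18 cholesterol synthesis genes none rose and 3 fell (0 and 3 adjusted over the list alone, adjusted p = 0.202), MSMO1 by −1.71 ± 0.11 and HMGCS1 by −1.15 ± 0.10. Of 29 stress response genes 4 rose and 6 fell (4 and 7 adjusted over the list alone, adjusted p = 0.53), and of 14 fibroblast genes 4 rose and 1 fell (adjusted p = 0.53). Of 48 ribosomal protein genes none rose and 5 fell (0 and 4 adjusted over the list alone, adjusted p = 0.13). They were called with median centring (median 0.036, adjusted p = 0.0257) and with centring on detected probes (median −0.27, adjusted p = 0.00849). The medians of all genes were then 0.184 and −0.12, so the list median lay below that of all genes with either centring. PRC2 components (2 up and 3 down of 11, adjusted p = 0.988), basal epithelium genes (1 and 0 of 6, 0.222), neuroendocrine genes (0 and 1 of 7, 0.46), and blood cell genes (1 and 0 of 8, 0.76) did not pass it either. The same held for cancer-testis antigen genes (2 and 0 of 23, adjusted p = 0.486), immediate early and heat shock genes (2 and 3 of 20, 0.674) and oxidative phosphorylation genes (5 and 1 of 36, 0.46).

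In total, 3697 of 13789 genes changed with siEZH2 in LNCaP, 1973 higher and 1724 lower, and 655 and 754 of these by at least 1.5-fold. Centring arrays on the median of all probes moved the median of all genes from 0.022 to 0.184 and left 1689 genes, 1456 higher and 233 lower. Without replicate 1 or 3 of each group 2249 and 2433 genes were called.

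In C4-2B siEZH2 raised IGFBP3 by 1.87 ± 0.15, SOX8, a transcription factor, by 2.26 ± 0.13, and UGT2B15 and UGT2B17 by 1.72 ± 0.27 and 1.69 ± 0.14. TDO2, which degrades tryptophan, rose by 1.38 ± 0.12, IFIT1 by 1.41 ± 0.18, VASN by 1.36 ± 0.13 and the Notch-family repressor gene HES2 by 1.27 ± 0.16. The largest decreases were in PRADC1 (−1.99 ± 0.13), the stress transcription factor ATF5 (−1.88 ± 0.18), and the ribosome assembly factor EMG1 (−1.55 ± 0.13). Next came the ubiquitin-conjugating enzyme UBE2Q1 (−1.55 ± 0.12), ARPP19, an inhibitor of a mitotic phosphatase (−1.53 ± 0.10), and the clamp loader RFC5 (−1.51 ± 0.11). ARSB (−1.51 ± 0.10), ISCA1 (−1.50 ± 0.10) and ARF1 (−1.49 ± 0.09) fell as well. The small RNA gene SNAR-A1 fell by 1.52 ± 0.34 on the log2 scale (adjusted p = 0.00247). Its call was lost without replicate 2 of each group (−0.96, adjusted p = 0.161) and with median centring (adjusted p = 0.0672).

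Genes of cell division fell with siEZH2 in C4-2B. Of 39 DNA replication genes 1 rose and 23 fell (1 and 27 adjusted over the list alone, median −0.47, adjusted p of the list = 7.19e-15). The origin-firing factors CDC45 and GINS2 changed by −1.19 ± 0.13 and −1.18 ± 0.14. Of 38 mitosis genes none rose and 22 fell (0 and 24 adjusted over the list alone, median −0.35, adjusted p of the list = 1.89e-13). BIRC5 changed by −1.34 ± 0.10, CENPF by −1.32 ± 0.14 and the kinase AURKB by −0.86 ± 0.13. Of 26 p53 target genes 9 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.28, adjusted p of the list = 7.75e-05). SESN1 rose by 1.05 ± 0.10, TP53INP1 by 0.84 ± 0.16 and the cell cycle inhibitor CDKN1A by 0.62 ± 0.12. Of 35 androgen-induced genes 1 rose and 14 fell (2 and 14 adjusted over the list alone, median −0.19, adjusted p of the list = 1.12e-05). C1orf116 changed by −1.39 ± 0.12 and FKBP5 by −1.11 ± 0.11. Of 24 reported EZH2-repressed genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.10, or −0.074 with centring on detected probes, adjusted p of the list = 0.00378). NKD2 rose by 1.08 ± 0.17 and TIMP2 by 0.90 ± 0.13. With median centring this call was lost (adjusted p = 0.0725). Of 14 fibroblast genes 6 rose and none fell (7 and 0 adjusted over the list alone, median 0.32, adjusted p of the list = 0.000637). The collagen genes COL6A1 and COL6A2 rose by 0.97 ± 0.15 and 0.91 ± 0.19.

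Other groups were called in C4-2B with the preset correlation but not with an estimated one. Of 42 interferon-stimulated genes 11 rose and none fell (12 and 0 adjusted over the list alone, median 0.18, adjusted p of the list = 0.000865, and adjusted p = 0.118 with an estimated correlation). IFIT1 rose by 1.41, the peptide transporter TAP1 by 1.23 ± 0.11, CXCL10 by 1.03 ± 0.14 and OASL by at least 1.91-fold. Of 23 luminal genes 1 rose and 9 fell (2 and 9 adjusted over the list alone, median −0.20, or 0.045 with median centring, adjusted p of the list = 0.000865, and adjusted p = 0.0891 with an estimated correlation). KLK2, a prostate protease, changed by −0.61 ± 0.13. Of 25 hypoxia genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.16, or −0.015 with centring on detected probes, adjusted p of the list = 0.0239, and adjusted p = 0.531 with an estimated correlation). P4HA2, a collagen hydroxylase, rose by 1.16 ± 0.10. Of 6 basal genes 3 rose and none fell (3 and 0 adjusted over the list alone, median 0.33, adjusted p of the list = 0.0423, and adjusted p = 0.202 with an estimated correlation). SERPINB5, known as maspin, rose by 0.76 ± 0.15. Single arrays carried the hypoxia call, which was lost without siControl replicate 1 (adjusted p = 0.0782), siControl replicate 2 (0.176) or siEZH2 replicate 3 (0.194). The basal call was lost without siControl replicate 1 (0.058) or siEZH2 replicate 2 (0.0585). Androgen-repressed genes (3 up and 0 down) had an adjusted p of 0.0668, or 0.0322 without siControl replicate 2 and 0.044 with the stricter filter. Ribosomal protein genes (0 and 2, median −0.048) had 0.075, or 0.0299 without siEZH2 replicate 1 and 0.0326 with the mean of probes. For them it was 1.15e-05 with median centring and 2e-05 with centring on detected probes (median −0.35), where oxidative phosphorylation genes were called too (adjusted p = 0.0226). PRC2 components (1 and 4, 0.222), cholesterol synthesis genes (3 and 3) and stress response genes (5 and 2) did not pass the list test. MSMO1 fell in this line too, by 1.40 ± 0.11 on the log2 scale.

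The siRNA against EZH2 changed 2566 genes in C4-2B, 1394 higher and 1172 lower, 371 and 406 of them by at least 1.5-fold. Median centring left 1047 genes, 975 higher and 72 lower, and centring on detected probes gave 855 higher and 1263 lower. Without replicate 2 or 3 of each group 1078 and 1709 genes were called.

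The inhibitor arm asked what follows when the enzyme is given an inhibitor without an siRNA against its mRNA. Neither EZH2 protein nor histone methylation was measured. In LNCaP, EPZ6438 raised the chemokine genes CXCL8 (1.75 ± 0.17), CCL2 (1.73 ± 0.19) and CCL8 (1.42 ± 0.13), and the transcription factor SOX9 (1.27 ± 0.14) and SPOCK1, a matrix proteoglycan (1.30 ± 0.11). It also raised the iron-binding protein LCN2 (1.20 ± 0.12), IGFBP3 (1.10 ± 0.15) and DUSP5, a phosphatase acting on ERK (1.10 ± 0.20). SHROOM1 (1.19 ± 0.17) and PLCH2 (1.05 ± 0.19) also rose. UGT2B15 (−1.73 ± 0.27), UGT2B17 (−1.03 ± 0.14) and UGT2B10 (−0.91 ± 0.15), whose sequences are alike, fell, as did the metalloproteinase MMP16 (−1.09 ± 0.17). NOP56 (−0.91 ± 0.12), ALYREF (−0.90 ± 0.19), LYAR (−0.84 ± 0.13) and NAF1 (−0.81 ± 0.15) were also among the largest decreases. ALYREF was not called from the mean of its probes (−0.38, adjusted p = 0.111). ZNF679 (−0.80 ± 0.21) was lost without background correction (adjusted p = 0.057) and FOXRED2 (−0.79 ± 0.20) was lost with centring on detected probes (adjusted p = 0.0512). Leaving out all arrays of 1 replicate number also ended the calls of PLCH2, NAF1, ALYREF, ZNF679 and FOXRED2.

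Androgen-induced genes rose with EPZ6438 in LNCaP, 14 of 35 higher and none lower (19 and 2 adjusted over the list alone, median 0.41, adjusted p of the list = 7.11e-13). PMEPA1, a brake on TGF-beta signalling, rose by 0.96 ± 0.13 and the androgen-regulated proteases KLK2 and TMPRSS2 by 0.77 ± 0.13 and 0.73 ± 0.12. Interferon-stimulated genes rose, 15 of 42 higher and none lower (22 and 1 adjusted over the list alone, median 0.31, adjusted p of the list = 1.14e-09). CXCL10 rose by 1.00 ± 0.14 and IRF1 by 0.89 ± 0.20. Reported EZH2-repressed genes rose, 9 of 24 higher and none lower (10 and 0 adjusted over the list alone, median 0.24, adjusted p of the list = 5.86e-06), including BMPR1B (0.81 ± 0.13) and VASH1 (0.62 ± 0.13). Fibroblast genes rose, 4 of 14 higher and none lower (5 and 0 adjusted over the list alone, median 0.28, adjusted p of the list = 7.33e-06). Smooth muscle actin ACTA2 rose by 1.04 ± 0.15 and the mesenchymal factors TWIST1 and SNAI2 by 0.73 ± 0.10 and 0.71 ± 0.12. Luminal genes also rose, 9 of 23 higher and 1 lower (13 and 2 adjusted over the list alone, median 0.40, adjusted p of the list = 1.83e-05). DNA replication genes fell, 18 of 39 lower and none higher (27 and 0 adjusted over the list alone, median −0.43, adjusted p of the list = 4.69e-17). Thymidine kinase TK1 changed by −0.72 ± 0.19 and MCM10 by −0.70 ± 0.16. Mitosis genes fell, 10 of 38 lower and none higher (28 and 0 adjusted over the list alone, median −0.32, adjusted p of the list = 2.16e-16). The cyclin CCNA2 changed by −0.68 ± 0.13 and AURKB by −0.58 ± 0.13. Cholesterol synthesis genes were called lower with 1 member past the test, MSMO1 at −0.41 ± 0.11 (median −0.18, adjusted p of the list = 0.0134, and adjusted p = 0.167 with an estimated correlation). The cholesterol call was lost without DMSO replicate 2 (adjusted p = 0.121). Androgen-repressed genes had a median of 0.065 but a mean of −0.21 (1 higher and 3 lower, adjusted p of the list = 0.222). They were called lower with the stricter filter (median −0.37, adjusted p = 0.0244) and with centring on detected probes (0.0346). Ribosomal protein genes were called with median centring alone (adjusted p = 0.00397), and oxidative phosphorylation genes with either centring (0.00582 and 0.00425) and without EPZ6438 replicate 1 (0.0218).

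EPZ6438 changed 924 genes in LNCaP, 555 higher and 369 lower, 182 and 70 of them by at least 1.5-fold. The count moved with single arrays, to 1783 without EPZ6438 replicate 1, 489 and 399 without DMSO replicate 1 or 3, and 293 without EPZ6438 replicate 3, and to 109 without replicate 3 of each group. A fit of the 6 compared arrays alone called 56 genes, 42 higher and 14 lower, and median centring 28, 26 higher and 2 lower. The SD of the log2 difference between arrays was 0.307 and 0.351 for replicate 1 against replicates 2 and 3, and 0.235 between replicates 2 and 3.

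Genes of the amino acid and unfolded protein stress response were among those EPZ6438 lowered most in C4-2B. INHBE, a stress-induced activin gene, changed by −2.94 ± 0.11 and the stress transcription factor DDIT3 by −2.58 ± 0.14. TRIB3, a pseudokinase it induces, changed by −2.57 ± 0.16 and FGF21, a stress-induced hormone, by −2.43 ± 0.09. The glycine transporter SLC6A9 (−2.36 ± 0.15), the serine synthesis enzyme PSPH (−2.17 ± 0.16), the cysteine synthesis enzyme CTH (−2.02 ± 0.14) and PCK2, a mitochondrial carboxykinase (−1.86 ± 0.15) fell as well. So did BEST1, a chloride channel (−2.57 ± 0.16), and the transcription factor BCL11B (−2.39 ± 0.17), which are on no stress list. The DMSO cultures of C4-2B stood high for the stress genes. DDIT3 had a log2 intensity of 10.2 ± 0.26 (SD, n = 3) with DMSO, 7.59 ± 0.30 with EPZ6438 and 7.94 ± 0.13 with siControl. TXNIP, a glucose-responsive inhibitor of thioredoxin, rose by 2.89 ± 0.17, the matrix protein THBS1 by 2.49 ± 0.16 and the kinase SGK1 by 2.47 ± 0.13. The receptor S1PR3 rose by 2.34 ± 0.12, IGFBP5 by 2.30 ± 0.14, TMEFF2 by 2.15 ± 0.08 and the chemokine gene CXCL12 by 2.08 ± 0.15. TRIB2 rose by 1.92 ± 0.16 and the co-receptor NRP1 by 1.84 ± 0.12. PCDHB2, a protocadherin, rose by at least 3.57-fold.

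Of 29 stress response genes 1 rose and 19 fell with EPZ6438 in C4-2B (2 and 19 adjusted over the list alone, median −0.84, adjusted p of the list = 8.14e-20). Of 35 androgen-induced genes 20 rose and 1 fell (23 and 1 adjusted over the list alone, median 0.44, adjusted p of the list = 1.11e-12). The channel TRPM8 rose by 1.61 ± 0.12, MAF by 1.46 ± 0.11, TMPRSS2 by 1.23 ± 0.12 and KLK2 by 1.21 ± 0.13. Of 38 mitosis genes 1 rose and 25 fell (1 and 27 adjusted over the list alone, median −0.43, adjusted p of the list = 3.46e-14). The centromere histone CENPA changed by −1.02 ± 0.11 and CCNB2 by −0.84 ± 0.09. Of 18 cholesterol synthesis genes 7 rose and none fell (8 and 0 adjusted over the list alone, median 0.31, adjusted p of the list = 9.36e-05). INSIG1 rose by 1.03 ± 0.14 and LSS by 0.69 ± 0.14, while 2 probes of MSMO1 gave 0.79 and −0.39. Of 23 luminal genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.17, adjusted p of the list = 0.000213), including ACP3, prostatic acid phosphatase (1.00 ± 0.09). Of 24 reported EZH2-repressed genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.16, adjusted p of the list = 0.00499), BMPR1B by 1.27 ± 0.13 and WNT5A by 0.96 ± 0.13. Of 14 fibroblast genes 3 rose and none fell (4 and 0 adjusted over the list alone, median 0.14, adjusted p of the list = 0.00499), COL5A1 by 1.44 ± 0.14. Of 26 p53 target genes 1 rose and 6 fell (1 and 7 adjusted over the list alone, median −0.13, adjusted p of the list = 0.0259), SESN2, also a stress response gene, by −1.78 ± 0.16. The p53 call was lost without replicate 1 of each group (adjusted p = 0.0574) and without background correction (adjusted p = 0.0536).

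Of 39 DNA replication genes 11 rose and none fell with EPZ6438 in C4-2B (11 and 0 adjusted over the list alone, median 0.16, adjusted p of the list = 0.00788, and adjusted p = 0.453 with an estimated correlation). The helicase subunit MCM4 rose by 0.89 ± 0.16. Of 25 hypoxia genes 7 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.24, adjusted p of the list = 0.00788, and adjusted p = 0.435 with an estimated correlation). LOX changed by 0.83 ± 0.11 and DDIT4 by −1.12 ± 0.26. Single DMSO arrays carried the replication call, which was lost without replicate 1 (adjusted p = 0.174) or 2 (0.07), and the hypoxia call was lost without DMSO replicate 1 (0.0819) or EPZ6438 replicate 3 (0.111). Interferon-stimulated genes did not pass the list test (7 higher and 2 lower of 42, adjusted p = 0.282). Immediate early and heat shock genes (4 and 1 of 20) had an adjusted p of 0.0505, or 0.0342 without DMSO replicate 3 and 0.0293 without EPZ6438 replicate 2. It lay between 0.0281 and 0.0481 with the mean of probes, either centring, the authors' values and the replicate block. Basal genes (2 and 0 of 6) had 0.0914, or 0.0239 without DMSO replicate 2 and 0.0414 without EPZ6438 replicate 1. Androgen-repressed genes had 0.14 (1 and 4 of 11, median 0.026), or 0.013 with the stricter filter (median −0.445) and 0.0479 with median centring, with UGT2B17 at −1.59 ± 0.14. The inhibitor changed 2100 genes in C4-2B, 1124 higher and 976 lower, 447 and 337 by at least 1.5-fold. Median centring left 265, 181 higher and 84 lower, and without replicate 1 of each group 1200 genes were called and without replicate 2 of each group 1018.

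**Figure D2:**
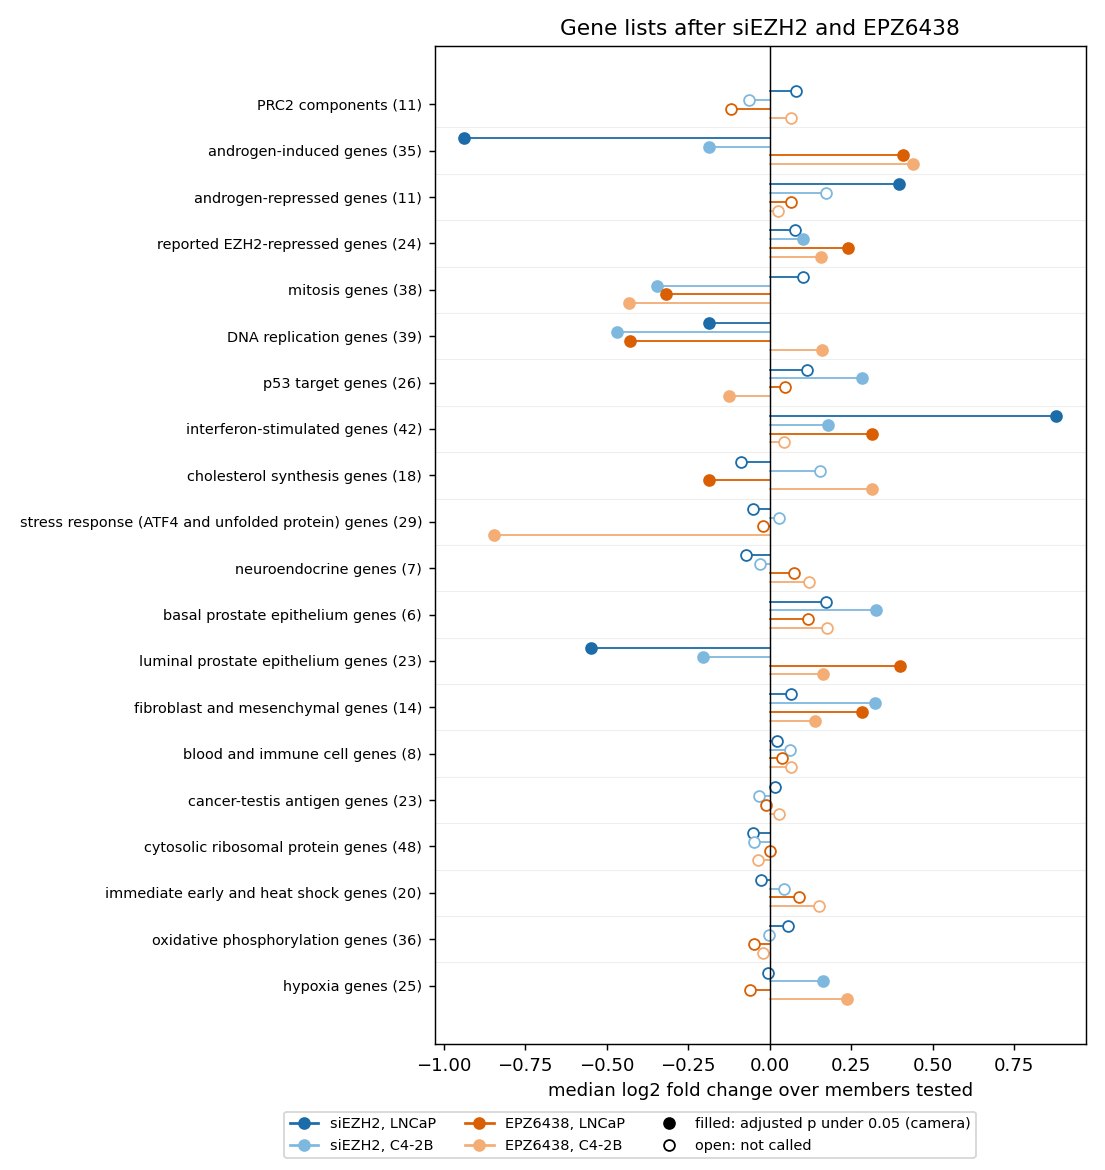
Median log2 change of each gene list (x axis) with siEZH2 and with EPZ6438 in LNCaP and C4-2B, by list. Filled symbols mark lists with an adjusted p under 0.05 in the camera test, and androgen-induced genes lay at −0.94 and −0.19 with siEZH2 in LNCaP and C4-2B, and at 0.41 and 0.44 with EPZ6438.

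The question of the series, whether EZH2 acts beyond its methyltransferase activity, calls for the difference between depletion and inhibition, tested here as the siEZH2 change minus the EPZ6438 change within a line. Higher and lower refer here to this difference of changes, not to levels. Depletion stands for siEZH2 against siControl. The labels name 1 siRNA against EZH2, so other effects of its duplex cannot be told apart from the lowering of EZH2. In LNCaP, UGT2B15 (3.79 ± 0.39), UGT2B17 (3.12 ± 0.20), CCL5 (3.16 ± 0.34) and OASL (2.57 ± 0.19) were higher with depletion than with inhibition. PKM (−2.69 ± 0.25), TARP (−2.66 ± 0.18), PGC, a pepsinogen (−2.61 ± 0.21), YWHAE (−2.51 ± 0.30) and TRIM49D1 (−2.36 ± 0.29) were lower. Androgen-induced genes moved apart, 28 of 35 lower and none higher with depletion than with inhibition (29 and 0 adjusted over the list alone, median −1.35, adjusted p of the list = 3.12e-32). The difference was −2.31 ± 0.15 for FKBP5 and −2.21 ± 0.18 for PMEPA1. Luminal genes followed, with 15 of 23 lower and 2 higher (16 and 2 adjusted over the list alone, median −1.06, adjusted p of the list = 5.13e-12). Interferon-stimulated genes were higher, 23 of 42 against 2 lower (25 and 2 adjusted over the list alone, median 0.72, adjusted p of the list = 8.87e-13). So were androgen-repressed genes (5 higher and 1 lower of 11, median 0.33, adjusted p of the list = 0.000395). Mitosis genes were higher, 16 against 2 of 38 (19 and 2 adjusted over the list alone, median 0.38, adjusted p of the list = 2.12e-05, and adjusted p = 0.196 with an estimated correlation). The control cultures of the arms differed for this list, which averaged 8.56 ± 0.03 (SD, n = 3) with DMSO, 8.25 ± 0.10 with EPZ6438, 7.71 ± 0.03 with siControl and 7.72 ± 0.04 with siEZH2. DNA replication genes were not called (6 higher and 3 lower of 39, median 0.32, adjusted p = 0.0934). They were called higher without background correction (0.0462), with median centring (0.0236) or centring on detected probes (0.013), and without DMSO replicate 2 (0.0401) or EPZ6438 replicate 1 (0.0322). Oxidative phosphorylation genes were called with median centring (0.0345) and without EPZ6438 replicate 1 (0.0322). The EZH2 difference was −0.74 ± 0.22 (adjusted p = 0.0202), and the call was lost without DMSO replicate 3 (adjusted p = 0.0617) or siEZH2 replicate 1 (0.0548) and without background correction (0.0777). The other EZH2 probes, adjusted over all kept probes, gave −0.60 (adjusted p = 0.0325) and −0.40 (0.471) in LNCaP. In C4-2B the same probes gave −0.94 (adjusted p = 0.00134) and −0.535 (0.327), so the last was called in neither line. RNA28SN5 differed by 4.18 ± 1.14 (adjusted p = 0.0115; 0.115 without replicate 1 of each group).

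In C4-2B, UGT2B17 (3.28 ± 0.20), UGT2B15 (3.08 ± 0.39) and the stress genes INHBE (2.99 ± 0.16) and DDIT3 (2.60 ± 0.20) were higher with depletion than with inhibition. For INHBE and DDIT3 this was the fall with EPZ6438 from the DMSO level, as their siEZH2 changes were 0.05 and 0.02. Lower were SGK1 (−3.73 ± 0.19), PIP, a prolactin-induced secretory protein (−2.29 ± 0.27), PRADC1 (−2.27 ± 0.18) and lipoprotein lipase LPL (−2.19 ± 0.18). Androgen-induced genes were lower, 22 of 35 against none higher (25 and 0 adjusted over the list alone, median −0.72, adjusted p of the list = 1.3e-17). The difference was −1.99 ± 0.15 for RHOU and −1.88 for TRPM8 and FKBP5. Luminal genes were lower, 11 against 1 of 23 (14 and 1 adjusted over the list alone, median −0.61, adjusted p of the list = 1.03e-07). Stress response genes were higher, 18 of 29 against none (21 and 0 adjusted over the list alone, median 1.15, adjusted p of the list = 2.34e-17). Higher too were p53 target genes, 9 of 26 against none (11 and 0 adjusted over the list alone, median 0.39, adjusted p of the list = 1.13e-06). DNA replication genes were lower, 20 of 39 against none (22 and 0 adjusted over the list alone, median −0.54, adjusted p of the list = 1.32e-15), GINS2 by −1.80 ± 0.20. Androgen-repressed genes were called higher (4 and 2 of 11, median 0.25, adjusted p of the list = 0.0381, and adjusted p = 0.0651 with an estimated correlation). This call was lost without DMSO replicate 3 (adjusted p = 0.0581) or siControl replicate 3 (0.0701). The replicate block (0.0842), no background correction (0.0797), median centring (0.0627) and the mean of probes (0.0592) also ended it. Cholesterol synthesis genes were called lower (0 and 3 of 18, median −0.12, or 0.12 with median centring, adjusted p of the list = 0.0164, and adjusted p = 0.184 with an estimated correlation). It was lost without DMSO replicate 1 (adjusted p = 0.0593). Mitosis genes (6 and 5, adjusted p = 0.905) and interferon-stimulated genes (10 and 1, adjusted p = 0.104; 0.0402 without siControl replicate 2) did not pass the list test. Ribosomal protein genes (adjusted p = 0.773) were called with median centring (0.0135) and centring on detected probes (0.00697). The control cultures of the inhibitor and siRNA arms differed in this line, as the androgen-induced list averaged 7.91 ± 0.01 (SD, n = 3) with DMSO, 8.43 ± 0.04 with EPZ6438, 6.90 ± 0.05 with siControl and 6.64 ± 0.03 with siEZH2.

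The test of the difference called 2557 genes in LNCaP (1221 higher and 1336 lower) and 1919 in C4-2B (917 higher and 1002 lower). Median centring left 268 (190 and 78) and 182 (122 and 60) for LNCaP and C4-2B. Leaving out 1 replicate of each group lowered the counts to between 1331 and 1421 in LNCaP and to as few as 838 in C4-2B.

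Genes lowered by siEZH2, and lowered more than by EPZ6438, are those the activator question concerns most. They numbered 1052 in LNCaP (61% of the genes lowered by siEZH2) and 571 in C4-2B (48.7%), and 310 were shared, where 43.6 would be shared if the lines were independent. Falls with siEZH2 were themselves shared between lines (693, or 146.5 if independent), as were rises (686, or 199.5). This reference, and the one for raised genes below, is therefore too low to size the overlap. Androgen-induced genes made up 13 of the 35 measured (Fisher's exact test, adjusted p = 5.53e-12) and luminal genes 6 of 23 (adjusted p = 8.99e-05). EPZ6438 raised 106 of the 1052 in LNCaP and 111 of the 571 in C4-2B, against 555 and 1124 of all 13789 genes. The sets favour genes that EPZ6438 raised, since they were chosen by a negative difference between the treatments. In the opposite direction, 948 genes in LNCaP and 430 in C4-2B were raised by siEZH2 and more than by EPZ6438, and 150 were shared (29.6 if independent). These included 7 of 42 interferon-stimulated genes (Fisher's exact test, adjusted p = 6.14e-06), 3 of 11 androgen-repressed genes (adjusted p = 0.00195) and 3 of 24 reported EZH2-repressed genes (adjusted p = 0.0144). The 3 androgen-repressed genes include UGT2B15 and UGT2B17, whose sequences are alike. Fisher's exact test takes genes as independent, and members of a list may move together, so these p-values may be too small. Leaving out all arrays of 1 replicate number gave 144 to 172 shared lowered and 42 to 65 shared raised genes, and median centring gave 1 and 9. Other effects of the siRNA duplex could recur in both lines, so the shared sets do not separate them from the lowering of EZH2.

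**Figure D3:**
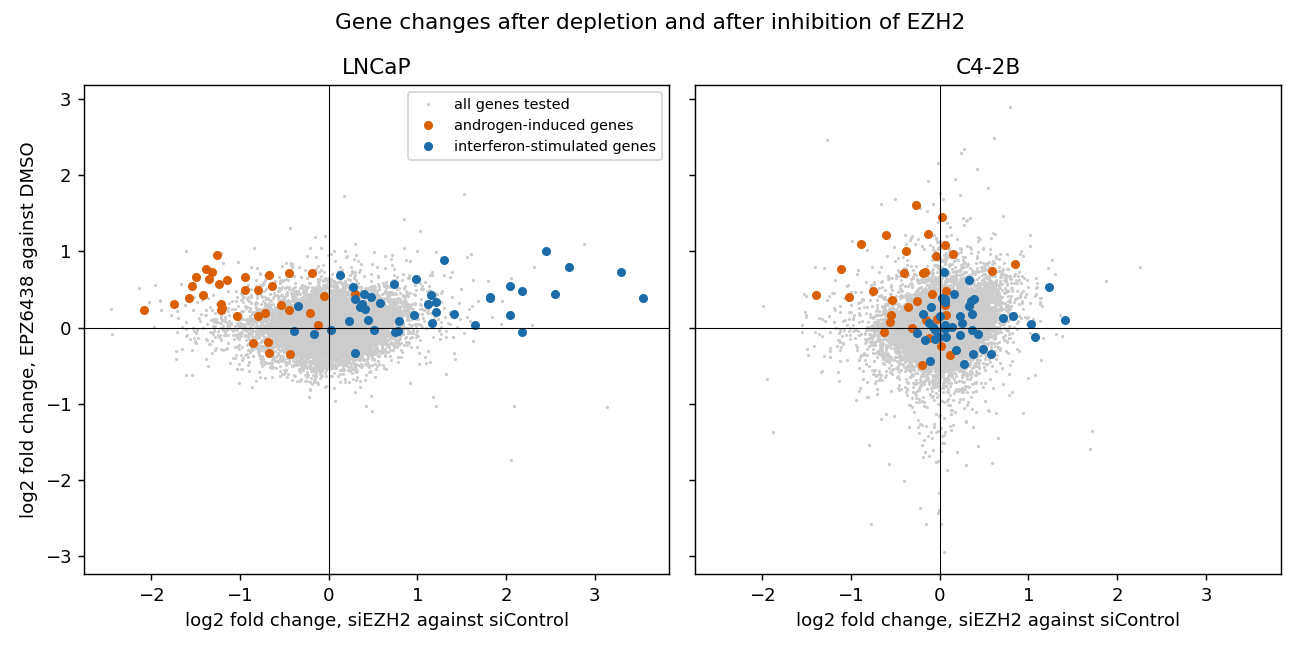
Log2 fold change with EPZ6438 against DMSO (y axis) and with siEZH2 against siControl (x axis) for each gene tested (grey), in LNCaP and C4-2B; orange points are androgen-induced and blue points interferon-stimulated genes. Across genes the correlation was 0.088 in LNCaP and 0.166 in C4-2B.

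Depletion and inhibition also moved some genes the same way. In LNCaP 148 genes rose and 64 fell with both, where 79.4 and 46.1 would be shared if independent, and 163 went opposite ways (122.2 if independent). In C4-2B 306 rose and 156 fell with both (113.6 and 83 if independent), and 196 went opposite ways (194.2). Both treatments in both lines raised 28 genes and lowered 15. If all 4 comparisons were independent, 0.65 and 0.28 would be shared. Each treatment's changes were shared between lines, however, so this reference is too low to size the overlap of depletion and inhibition. IGFBP3 rose by 2.88, 1.87, 1.10 and 0.61 with siEZH2 in LNCaP and C4-2B and with EPZ6438 in LNCaP and C4-2B. SOX9 rose by 1.03, 0.57, 1.27 and 1.03, the metalloproteinase inhibitor TIMP2 by 0.79, 0.90, 0.52 and 0.96, and the thrombospondin gene THBS1 by 1.21, 0.61, 0.99 and 2.49. ATF5 changed by −0.86, −1.88, −0.77 and −1.36, BIRC5 by −1.04, −1.34, −0.36 and −0.59 and AURKB by −0.49, −0.86, −0.58 and −0.67. The 212 genes changed the same way in LNCaP became 421 without EPZ6438 replicate 1, 111 and 92 without DMSO replicate 1 or 3, and 77 without EPZ6438 replicate 3.

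The genes changed in both lines were counted for each treatment. With siEZH2, 686 genes rose and 693 fell in both lines (199.5 and 146.5 if independent) and 46 went opposite ways, and the correlation of changes across genes, which are not independent replicates, was 0.585. With EPZ6438, 200 rose and 65 fell in both (45.2 and 26.1 if independent), 45 went opposite ways and the correlation was 0.287. The 265 genes changed alike by EPZ6438 became 442 without LNCaP EPZ6438 replicate 1, 114 without LNCaP EPZ6438 replicate 3, and 162 and 143 without LNCaP DMSO replicate 1 or 3.

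The siEZH2 change in C4-2B minus that in LNCaP was tested for each gene. The difference was −3.21 ± 0.34 for CCL5, which changed by 3.54 in LNCaP and 0.33 in C4-2B. IFI27 rose by 2.04 in LNCaP and was undetected with siEZH2 in C4-2B, and IFNB1 was undetected on all C4-2B arrays. Interferon-stimulated genes as a list differed, 24 of 42 lower and none higher (27 and 1 adjusted over the list alone, median −0.71, adjusted p of the list = 1.2e-25). TRIM51 (2.20 ± 0.19), TRIM48 (2.13 ± 0.21) and NDRG1, a stress and androgen-responsive gene (1.94 ± 0.32), fell in LNCaP, while their changes in C4-2B were 0.31, 0.24 and 0.59. TRIM48 stood at 4.41 in C4-2B and 7.91 in LNCaP with siControl, and TARP was undetected with siControl and siEZH2 in C4-2B. Androgen-induced genes differed, 18 of 35 higher and none lower (25 and 0 adjusted over the list alone, median 0.62, adjusted p of the list = 2.63e-19). So did luminal genes (11 higher and 2 lower of 23, median 0.51, adjusted p of the list = 3.44e-06). With siControl the androgen-induced list averaged 6.90 ± 0.05 (SD, n = 3) in C4-2B and 8.56 ± 0.03 in LNCaP. The luminal list averaged 8.10 ± 0.08 and 9.54 ± 0.03. The smaller falls in C4-2B may reflect these lower starting levels, which was not tested. Mitosis genes differed the other way, 10 of 38 lower and none higher (22 and 0 adjusted over the list alone, median −0.41, adjusted p of the list = 3.18e-13). So did androgen-repressed genes (0 and 2 of 11, 0 and 5 adjusted over the list alone, median −0.47, adjusted p of the list = 0.00101). With siControl the mitosis list averaged 8.92 ± 0.08 (SD, n = 3) in C4-2B and 7.71 ± 0.03 in LNCaP, and the DNA replication list 8.84 ± 0.03 and 7.93 ± 0.02. With siEZH2 in C4-2B the mitosis list averaged 8.53 ± 0.07, still above LNCaP with siControl. Whether these starting levels account for the differences was not tested. The ribosomal RNA genes RNA28SN5 (−5.08 ± 1.14, adjusted p = 0.00889) and RNA18SN5 (−2.39 ± 0.55, adjusted p = 0.0109) differed too, with calls lost without replicate 2 of each group (adjusted p = 0.0755 and 0.092). DNA replication (adjusted p of the list = 3.08e-06), cholesterol synthesis (0.0141), fibroblast (0.0224) and hypoxia genes (0.00085) were called with the preset correlation and not with an estimated one (adjusted p = 0.219, 0.195, 0.0744 and 0.331). Oxidative phosphorylation genes were called with median centring (adjusted p = 0.0219) and centring on detected probes (0.00236), and cancer-testis genes without replicate 1 of each group (0.0293). In all 803 genes differed, 437 higher and 366 lower, or 79 with median centring, 22 higher and 57 lower. Single arrays moved this count to 534, 512 and 484 without LNCaP siControl replicates 1, 2 and 3, and to 475 and 524 without LNCaP siEZH2 replicates 1 and 3. It moved to 446 without C4-2B siControl replicate 2 and to 500 and 530 without C4-2B siEZH2 replicates 2 and 3.

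For EPZ6438, S1PR3 (2.21 ± 0.17), IGFBP5 (2.13 ± 0.19) and TXNIP (2.12 ± 0.23) rose more in C4-2B, and CXCL12 rose there and was undetected with EPZ6438 in LNCaP. The difference was negative for BEST1 (−2.87 ± 0.22), DDIT3 (−2.73 ± 0.20), INHBE (−2.73 ± 0.16) and TRIB3 (−2.45 ± 0.22). These fell in C4-2B, and their changes in LNCaP were 0.29, 0.16, −0.21 and −0.12. Stress response genes differed, 16 of 29 lower and none higher (20 and 0 adjusted over the list alone, median −0.79, adjusted p of the list = 1.65e-19). DNA replication genes differed, 20 of 39 higher and none lower (22 and 0 adjusted over the list alone, median 0.55, adjusted p of the list = 3.45e-16), MCM4 by 1.47 ± 0.22. So did cholesterol synthesis genes (6 and 0 of 18, 9 and 0 adjusted over the list alone, median 0.41, adjusted p of the list = 2.48e-07) and, in the other direction, p53 target genes (1 and 3 of 26, median −0.16, adjusted p of the list = 0.0133, or 0.0811 without replicate 1 of each group). Mitosis genes were called without LNCaP EPZ6438 replicate 3 (adjusted p = 0.0131). Interferon-stimulated (median −0.20, adjusted p of the list = 0.00213), hypoxia (0.23; 0.00213) and androgen-induced genes (0.13; 0.045) were called with the preset correlation and not with an estimated one (adjusted p = 0.242, 0.585 and 0.42). The androgen call was lost without 6 single arrays, by most without LNCaP EPZ6438 replicate 1 (adjusted p = 0.272) or 2 (0.154) and C4-2B EPZ6438 replicate 2 (0.108). In all 923 genes differed, 447 higher and 476 lower, or 35 with median centring, 15 higher and 20 lower. Without replicate 1, 2 or 3 of each group 322, 300 and 493 genes differed.

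The difference between control cells of the lines was taken from the DMSO and siControl arrays together, C4-2B minus LNCaP, with 6 arrays per line. Some of it depended on the kind of control culture. Cancer-testis antigens PAGE1 (6.03 ± 0.22) and MAGEA1 (4.10 ± 0.12), from families whose members share sequence, were higher in C4-2B. CT45A3 stood at 9.26 in C4-2B and 4.98 in LNCaP with DMSO, and was undetected with siControl in LNCaP. Also higher were the amino acid transporter SLC7A5 (4.79 ± 0.14) and the transcription factor ASCL2 (4.44 ± 0.09). The metallothionein MT1G (−3.90 ± 0.11) and the ephrin EFNB2 (−3.77 ± 0.06) were lower. TMEFF2, a prostate membrane protein, TARP and the imprinted gene PEG3 were undetected with siControl in C4-2B. With DMSO they stood at 7.09, 4.56 and 5.12 in C4-2B against 11.05, 9.59 and 9.52 in LNCaP. Androgen-induced genes were lower, 28 of 35 against 1 higher (30 and 2 adjusted over the list alone, median −0.87, adjusted p of the list = 1.43e-12), with HPGD at least 6.27-fold lower. Their median was −0.15 between DMSO cultures and −1.65 between siControl cultures. Luminal genes were lower, 14 against 3 of 23 (15 and 3 adjusted over the list alone, median −0.55, adjusted p of the list = 5.09e-06), with a median of −0.051 between DMSO cultures and −0.98 between siControl cultures. KLK3, which encodes PSA, stood at 8.19 in C4-2B and 8.34 in LNCaP with DMSO, and at 5.24 and 9.36 with siControl. Interferon-stimulated genes were lower, 31 against 3 of 42 (32 and 3 adjusted over the list alone, median −0.66, adjusted p of the list = 1.02e-10). IFIT1 stood at 5.25 in C4-2B and 7.80 in LNCaP with siControl, and was undetected with DMSO in C4-2B. Mitosis genes were called higher over both kinds of culture, 31 against 1 of 38 (32 and 1 adjusted over the list alone, median 0.46, adjusted p of the list = 3.37e-10). The siControl cultures carried this call (median 1.21), and between DMSO cultures the median was −0.16. Lower were p53 target genes, 14 against 3 of 26 (median −0.29, adjusted p of the list = 0.00168), and higher were cancer-testis genes, 12 against 4 of 23 (13 and 4 adjusted over the list alone, median 0.40, adjusted p of the list = 0.00128). Stress response (19 higher and 6 lower of 29, adjusted p of the list = 0.00185), cholesterol synthesis (1 and 12 of 18, 0.00185) and reported EZH2-repressed genes (4 and 9 of 24, 0.045) were called with the preset correlation and not with an estimated one (adjusted p = 0.306, 0.0856 and 0.0947). Androgen-repressed genes were called with median centring (adjusted p = 0.0299). The stress response median was 1.26 between DMSO cultures and −0.21 between siControl cultures, so that call came from the C4-2B DMSO cultures. The EZH2-repressed median of −0.093 turned to 0.002 with centring on detected probes, and its call was lost without LNCaP DMSO replicate 2 (adjusted p = 0.0534) or C4-2B DMSO replicate 1 (0.0519). EZH2 was called higher in C4-2B by 0.42 ± 0.11 (adjusted p = 0.0027; 0.32 and adjusted p = 0.132 with median centring), which came from siControl (7.48 against 6.69) rather than DMSO cultures (7.18 against 7.13). In all 6825 genes differed, 3399 higher and 3426 lower, or 1294 and 2368 with median centring. Of the 6825, 1134 had opposite signs between DMSO and between siControl cultures.

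**Figure D4:**
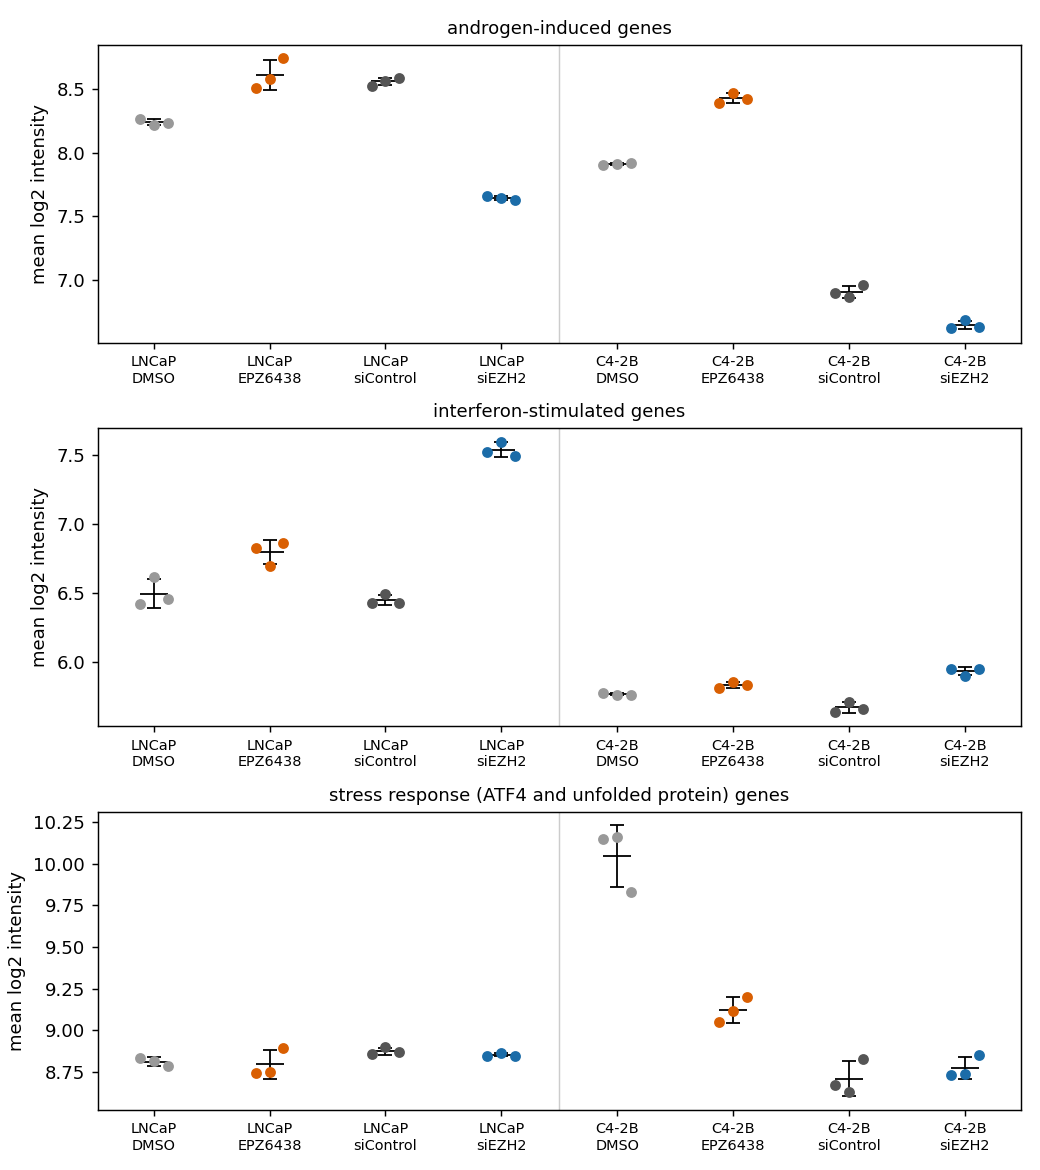
Mean normalised log2 intensity of the androgen-induced, interferon-stimulated and stress response lists on each array (points, 3 per group; lines, group mean ± SD), by cell line and treatment. Interferon-stimulated genes averaged 6.45 with siControl and 7.54 with siEZH2 in LNCaP, and stress response genes 10.05 with DMSO and 9.12 with EPZ6438 in C4-2B.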

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

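The counts of other array splits and the test of the response of replicate 1 were planned; the other tests in this part, on the interferon and stress genes and on the brightness of replicate 1, were chosen after the results were seen.

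The cell lines differed in their response by a test of the difference itself for 803 genes with siEZH2 and 923 genes with EPZ6438. The siEZH2 median in C4-2B minus that in LNCaP was 0.62 for androgen-induced, −0.47 for androgen-repressed, −0.41 for mitosis, −0.26 for DNA replication, −0.71 for interferon-stimulated, 0.29 for cholesterol synthesis, 0.51 for luminal, 0.16 for fibroblast and 0.20 for hypoxia genes. With an estimated correlation DNA replication (adjusted p = 0.219), cholesterol synthesis (0.195), fibroblast (0.0744) and hypoxia genes (0.331) were not called. For EPZ6438 it was 0.13 for androgen-induced, 0.55 for DNA replication, −0.16 for p53 target, −0.20 for interferon-stimulated, 0.41 for cholesterol synthesis, −0.79 for stress response and 0.23 for hypoxia genes. Androgen-induced (adjusted p = 0.42), interferon-stimulated (0.242) and hypoxia genes (0.585) were not called with an estimated correlation. With siControl the androgen-induced and luminal lists stood lower in C4-2B than in LNCaP, and the mitosis and DNA replication lists higher, which bears on their siEZH2 differences. Among 28 named genes, the siEZH2 change was higher in C4-2B for TRIM51 (2.20), TRIM48 (2.13), TARP (2.12), TRIM49D1 (1.99), NDRG1 (1.94), TRIM49D2 (1.93), PLPPR1 (1.26), TDO2 (1.22), PKM (1.09), VASN (1.03), FKBP5 (0.97), KRT19 (0.96) and ARF1 (0.95). It was lower there for ARSB (−0.52), RFC5 (−0.54), IGFBP3 (−1.01), ATF5 (−1.02), IFIT1 (−1.14), PLAAT4 (−1.42), CXCL10 (−1.43), IFIT2 (−1.89), RSAD2 (−2.04), OASL (−2.22), IFI27 (−2.22), IFNB1 (−2.33), RNA18SN5 (−2.39), CCL5 (−3.21) and RNA28SN5 (−5.08). Among 30 named genes, the EPZ6438 change was higher in C4-2B for S1PR3 (2.21), IGFBP5 (2.13), CXCL12 (2.12), TXNIP (2.12), TRIB2 (2.04), PCDHB2 (1.87), SGK1 (1.75), TMEFF2 (1.70), NRP1 (1.52), THBS1 (1.495), UGT2B10 (1.33), FOXRED2 (1.12), MMP16 (1.05), NOP56 (1.04) and LYAR (0.63). It was lower there for SHROOM1 (−1.08), LCN2 (−1.43), PCK2 (−1.44), CCL8 (−1.49), CXCL8 (−1.74), CCL2 (−1.76), PSPH (−1.79), CTH (−2.04), SLC6A9 (−2.35), BCL11B (−2.42), FGF21 (−2.42), TRIB3 (−2.45), INHBE (−2.73), DDIT3 (−2.73) and BEST1 (−2.87). These sizes are fitted values, and are not exact where no array of a compared group detected the gene. For siEZH2 this holds for TRIM49D1, TRIM49D2, TARP, PLPPR1, TDO2, IFI27, IFNB1, OASL and RSAD2. For EPZ6438 it holds for CXCL12, TRIB2, PCDHB2, BCL11B, FGF21, LCN2, CCL2 and SHROOM1. Outside the named genes, of 7449 probes without a gene, 688 and 374 were called with siEZH2 in LNCaP and C4-2B, and 74 and 268 with EPZ6438.

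In 10 splits of the 6 arrays of each treatment comparison, the real split alone gave as many genes, and 10 splits are too few for a share under 0.05. The real count was 3697 against a highest other of 0 for siEZH2 in LNCaP, 2566 against 0 in C4-2B, 924 against 5 for EPZ6438 in LNCaP and 2100 against 129 in C4-2B, and 1 of 10 splits reached it in each case. Of 100 splits, the real one included, 4 gave as many genes as the 2557 with a different effect of depletion and inhibition in LNCaP (highest other 2903). For the 1919 in C4-2B 1 split did (1710), as for the 6825 between control cells (4399) and the 310 lowered in both lines (0). For the differences between lines, 9 of 100 splits gave as many as 803 genes (highest other 2795, 3 of them over 3 times the real count) and 5 as many as 923 (2365). A split mixes each compared pair of groups, and the median of the other splits was 0 genes in each case. Such splits ask whether the arrays differ by group at all, not whether 2 real effects differ. Chance is therefore not called excluded for the differences between treatments or lines. The splits other than the real one that reached a real count all kept the groups of 1 of the 2 compared effects whole (3, 8 and 4 splits), so the structure of the samples they carried was that treatment effect. Splits that kept neither effect whole gave at most 0 genes against 803 and 114 against 923.

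Interferon-stimulated genes rose with siEZH2 in LNCaP, with a median of 1.16 over the 34 members that rose. If loss of methylation activity were the whole cause and EPZ6438 removed it, EPZ6438 should have raised them by at least 0.5 times as much, but their median was 0.33 (13 of 34 called), below that bound by more than the SE over members of 0.071. Members chosen by their rise raise the bound, but over all 42 tested members the medians were 0.88 and 0.31, also below it, by 0.125 (SE 0.068), and the removal of methylation at this dose and time was not measured. The SEs over members, here and for the stress genes below, are over genes that may move together and leave out the spread between arrays. Over arrays the list averaged 6.50 ± 0.10 (SD, n = 3) with DMSO and 6.80 ± 0.09 with EPZ6438. It averaged 6.45 ± 0.04 with siControl and 7.54 ± 0.05 with siEZH2. The EPZ6438 arrays include replicate 1, which stood apart. Sensing of the siRNA duplex by the cells remains a candidate explanation, since the labels name only 1 siRNA against EZH2 and no value here separates it from the lowering of EZH2.

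The 19 stress response genes that fell with EPZ6438 in C4-2B, with a median of −1.54, may reflect DMSO cultures under stress. In C4-2B these members were higher with DMSO than with siControl by a median of 1.74, which exceeded the same difference in LNCaP by 1.84 (SE over members 0.19), and all 19 went that way. With EPZ6438 they lay 0.41 (SE 0.138) above that reference, inside the bound of 0.5 set for this explanation but by less than 1 SE, so it cannot be told apart from an effect of EPZ6438 in C4-2B. The DMSO arrays enter both differences, and DMSO and siControl cultures came from separate experiments. In LNCaP the same members had a median EPZ6438 change of −0.12 (SE over members 0.063), so a fall of like size was not seen there. They were not raised with DMSO in LNCaP (median −0.10 against siControl). LNCaP therefore cannot show whether EPZ6438 lowers stress genes that are raised.

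Replicate 1 of LNCaP with EPZ6438 stood apart from replicates 2 and 3, and the count of called genes was 1783 without it against 924. A smaller response in this culture may account for it, since its slope on the EPZ6438 change in C4-2B was 0.153 against 0.219 and 0.206 for the others. That lay below their range but not below 0.5 times the lower one, the bound set for this explanation, so it was left open. A dimmer array was argued against, because 41.5% of its probes were detected, within the 41.4% to 43% of the other LNCaP arrays with DMSO or EPZ6438.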

How the results depend on the processing

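Leaving out single arrays and centring on the probes detected on all arrays were tests chosen after the results were seen; the other alternatives were planned. No called result was called in the opposite direction with any alternative, though some list medians changed sign with centring, the stricter filter or arrays left out. All 15 counts stayed within 1.5 times their value with no background correction, the authors' processed values, either other filter, the mean of probes, trend and robust variance, and the replicate block. Over all alternatives 99 of the counts moved by more than 1.5 times and 339 did not, 84 gene list results lost their call, 48 gained one and 3501 did neither, and 42 named gene results lost their call against 1323 that did not. The estimated correlation ended 21 list calls.

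With median centring the counts were 1689 and 1047 (siEZH2 in LNCaP and C4-2B), 28 and 265 (EPZ6438), 268 and 182 (depletion against inhibition), 79 and 35 (lines, siEZH2 and EPZ6438), 3662 (control cells), 1 and 9 (lowered and raised in both lines) and 10 and 34 (shared by treatments in LNCaP and C4-2B), and EZH2 with siEZH2 was −0.64 (adjusted p = 0.0536) and −0.69 (0.0533). It moved the median of all genes to 0.184 and 0.21 with siEZH2 and to 0.189 and 0.18 for depletion against inhibition. Centring on detected probes moved these to −0.12, −0.136, −0.132 and −0.101, and gave 355 and 1257 (EPZ6438), 466 and 459 (lines), 94 (raised in both) and 68 and 287 (shared). Array medians over those probes ran from 6.49 to 8.10 and over all probes from 4.30 to 4.52. Between 40.8% and 45.8% of probes were detected per array, so the median of all probes lay among undetected ones. Centring on that median therefore did not align the detected probes, and how far this lowered the counts was not tested. At 1.5-fold or more the counts were 1409, 777, 252, 784, 1701 (depletion against inhibition in LNCaP), 2179 (control cells), 157 and 46 (lowered and raised in both) and 53 and 89 (shared), by construction fewer. The compared arrays alone, with fewer samples, gave 56 and 1361 (EPZ6438), 480 (lines, EPZ6438) and 17 and 269 (shared).

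With arrays left out, counts ranged from 2249 to 3435 and 1078 to 2342 (siEZH2), 109 to 1783 and 1018 to 1906 (EPZ6438), 1331 to 2735 and 838 to 2148 (depletion against inhibition), 131 to 896 and 300 to 1210 (lines), 5394 to 6699 (control cells), 144 to 322 and 42 to 187 (lowered and raised in both) and 28 to 421 and 115 to 528 (shared). EZH2 ranged from −0.90 to −0.81 and −1.31 to −0.82 with siEZH2, and from −0.25 to −0.04 and −0.22 to 0.18 with EPZ6438. Omitting a replicate number leaves 2 arrays per group, and the cause of single shifts was not tested.

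Replicate numbers did not meet the bound set for pairing the arrays of an experiment, a correlation of residuals above 0.1 for every number. Correlations between arrays of the same number ran from 0.013 to 0.088 and −0.284 to 0.096 (siRNA, LNCaP and C4-2B) and from −0.119 to 0.32 and 0.037 to 0.312 (inhibitor). With 3 arrays per group this cannot exclude a pairing. As a block, replicate numbers gave 3764 and 2510 (siEZH2), 858 and 2078 (EPZ6438), 2456 and 1801 (depletion against inhibition), 670 and 838 (lines) and 6808 genes (control cells). The replicate block ended 3 list calls. They were androgen-repressed genes for depletion against inhibition in C4-2B (adjusted p = 0.0842) and androgen-induced genes for EPZ6438 between lines (0.0566). The last was reported EZH2-repressed genes between control cells (0.0539). A block of chip or scan was not run because the files name neither. Signal near background limits the dim genes, whose fold changes are understated.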

Other observations

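The choice of genes and the comparisons in this part were made after the results were seen, and none is a test of an explanation.

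Some genes had a larger fitted decrease with siEZH2 than EZH2 mRNA. EZH2 was dim (6.69 and 7.48 with siControl in LNCaP and C4-2B), and the offset shrinks the fold changes of dim probes, so the count depends on the brightness of each probe. Of the genes lowered in both lines, 61 fell more than EZH2 in each, 58 of these also fell more than with EPZ6438 in both lines, and 33 of the 58 were not called with EPZ6438 in either. ARF1, a GTPase of Golgi traffic, changed by −2.44 in LNCaP and −1.49 in C4-2B, against −0.09 and −0.29 with EPZ6438. CHMP3, a subunit of the membrane-remodelling ESCRT-III complex, changed by −1.70 and −1.48, the prefoldin-like protein UXT by −1.60 and −1.36, the iron-sulfur assembly protein ISCA1 by −1.51 and −1.50, and BECN1, which starts autophagy, by −1.52 and −1.14. IFNAR1, a subunit of the type I interferon receptor, changed by −1.44 and −1.19 while interferon-stimulated genes rose in LNCaP. PKM changed by −2.45 and −1.36 and YWHAE by −1.95 and −1.40. Whether any of these transcripts carries a match to the siRNA was not searched, since the duplex sequence is not in the labels.

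Genes held only by some cultures also stood out. TMEFF2, a prostate membrane protein abundant in LNCaP (11.1 to 12.0 in all groups), was at 7.09 with DMSO and 9.24 with EPZ6438 in C4-2B and undetected with siControl and siEZH2 there (4.23 and 4.21). FGF21 was at 7.09 ± 0.15 (SD, n = 3) with DMSO in C4-2B, 4.66 ± 0.11 with EPZ6438 and 4.20 with siControl. INHBE was at 8.02 ± 0.14, 5.08 and 4.42 in the same groups. The mineralocorticoid receptor gene NR3C2 rose in all 4 treatment comparisons, by 1.17 and 0.53 with siEZH2 and 0.47 and 0.56 with EPZ6438 in LNCaP and C4-2B, and the immune checkpoint gene CD276 by 1.28, 0.77, 0.48 and 0.77. The antigen-processing genes TAP1 (1.16, 1.23, 0.43 and 0.53) and HLA-E (0.48, 0.38, 0.40 and 0.37) rose in all 4 as well.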
